A study of Homo sapiens with 12 samples.

How the data were processed

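RNA was measured in 12 libraries of primary human CD4+ T cells from 3 healthy donors, resting or activated, each given DMSO or the combination of AZD4573 and SMAP-2, so that every donor gave 1 library to each of the 4 groups. Per the labels' protocols, libraries were made from polyadenylated RNA primed with oligo(dT), kept strand, carried unique molecular identifiers and covered the 3′ end of transcripts in single-end reads, and RNA concentrations were equalised before library preparation. All libraries carry 1 batch label. Per the submitters' processing notes, the tools were fastp 0.24.0, STAR 2.7, SAMtools 1.21, MultiQC 1.33 and featureCounts of Subread 2.1.1, with the genome build GRCh38, also named hg38. The roles and settings of these tools, and how molecular identifiers were used, are not given in the sources used here. The authors deposited 1 table with a row per gene (Ensembl identifier, position, strand, length, symbol) and 2 columns per library. The first kind of column holds the authors' deposited expected counts, in which 35.2% of values above 0 are not whole numbers (tolerance 0). How reads came to be shared between genes is not given in the sources used here. The other holds deposited CPM values, which the authors scaled by library total. Recomputing CPM from the counts matched that column within 9.82e-11 at every row. The planned test assumed whole counts, so the expected counts were rounded to whole numbers before the count tests.

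Of 78987 rows, 78894 have an Ensembl identifier, 92 are spike-in sequences and 1 is a plasmid sequence. The rows that name no gene held 0.00245% of all counts and were left out of library sizes and tests, as were 673 rows that could reveal a donor's sex, which left 78221 genes, 42760 rows of the table having a symbol. Gene positions are those of the deposited table, 1-based. Genes covered by others on the same strand were mostly listed at 0: of 20059 protein-coding genes 3501 have 0 counts in all libraries, which holds for 1422 of the 1720 (82.7%) covered by at least 90% on the same strand by other genes and for 1914 of the 16633 (11.5%) covered by under 10%. Of the 53 members of the gene lists with 0 counts in all libraries, 49 are covered by at least 90%, among them PPP2CA, LAT, SATB1, RIGI, SUPT4H1, ALDOA, RPL17 and RPS10, so their 0 does not show that they were not expressed. Values of partly covered genes (SDCBP2, FCGR3A, GNLY, CENPA, IFIT2, CCDC200, RPL36, HBD, PPP2R1A and others) are uncertain, as are those of near-identical copies (H2B histone genes, HBA1 and HBA2, HNRNPA1L3, HSPA1A and ribosomal protein genes). Library totals ran from 1345916 to 9071432. A count of 0 in a library allows up to 3 counts of its total, and over a group up to 3 counts of the group's total, which is the floor used for lower bounds. Floors cover counting error only. Within groups, replicate libraries correlated with r of 0.922 to 0.984 in log2 CPM.

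Differential expression was tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr per group (minimum count 10, minimum total 15), 12918 in all, libraries were scaled by TMM, and the quasi-likelihood test was run on 1 model of all 12 libraries with group and donor as terms (6 residual degrees of freedom). There were 4 contrasts: the drugs in resting cells, the drugs in activated cells, activation in DMSO cells and the interaction of drugs and activation. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, with 0.05 as threshold, SE is the absolute log2 fold change over the square root of F, and log2 CPM of single libraries used a prior count of 2. CPM in the results are counts over the TMM-scaled total of tested genes, not the deposited CPM, while shares of counts are unscaled. The pairing by donor comes from the labels. Same-numbered libraries deviated together from their group means (r 0.177 to 0.551 over all pairs of groups). The 35 gene lists, the contrasts and the rule for named genes were fixed before the data were examined. The lists cover RNA polymerase II elongation, PP2A, Integrator, immediate early genes, cell death, p53 targets, cytokines, activation receptors and factors, naive genes, T cell receptor signalling, S phase, G2/M, homologous recombination, ribosome biogenesis, ribosomal proteins, mitochondrially encoded genes, oxidative phosphorylation, glycolysis, cholesterol synthesis, interferon-stimulated genes, NF-κB targets, heat shock, endoplasmic reticulum stress, lysosome and autophagy, HIV host factors, histone genes, nuclear long non-coding RNAs, helper subsets, and markers of monocytes, B cells, NK and CD8+ cells, platelets, erythroid and dendritic cells. Lists were tested in the same design with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation per list and with fry. Adjusted p-values of lists are over the 35 lists of a contrast. Named genes were, per contrast, the 12 with the largest rise and the 12 with the largest fall (8 and 8 for the interaction) among called genes with the same direction in all 3 donors, a mean of at least 10 CPM and a named symbol, leaving out sex-linked, HLA and antigen receptor genes, then up to 4 members of each list with the smallest p, then CDK9, CCNT1, HEXIM1, MYC, MCL1, PPP2CA, PPP2R1A, IL2RA and MKI67. The text names a subset in order of rank, and some of these genes are not reported here.

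The procedure was tested on genes simulated independently from the real means and library sizes (5 draws, 12918 genes, 200 changed). For the drugs in resting cells it recovered 65.1% of 2-fold and 89.9% of 4-fold changes and 9.16% of called genes were unchanged ones, and for activated cells 71.7%, 91.3% and 11.5%, in both cases above the nominal 5%. A seeded list was called in each draw and 0 of 175 tests of other lists (camera) were, with correlated lists untested. Composition shares were compared with exact two-sided sign-flip tests over the 3 donors, whose smallest possible p is 0.25. The overlap of activation and drug effects in activated cells was set against 20 simulated unchanged drug groups. Alternatives were median-ratio, upper-quartile and library-size scaling, no filter (at least 1 count), a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, no donor block, a block per donor and state, fits on 6 libraries, mitochondrially encoded genes left out, each donor left out, a threshold of 0.01 and a 2-fold minimum, and, chosen after seeing the data, thinning to the lowest library total and leaving out genes covered by at least 10% on the same strand. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.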

Results

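Polyadenylated transcripts were counted at their 3′ ends in primary CD4+ T cells, the helper T cells of blood, from 3 healthy donors. From each donor, cells were kept for 48 h without stimulation (resting) or on plates coated with antibodies against CD3 and CD28, which engage the T cell receptor and its co-receptor (activated). Both kinds of culture then received, for 24 h, either 0.1% DMSO, the solvent, or 5 nM AZD4573 together with 5 µM SMAP-2. AZD4573 inhibits CDK9, the kinase that releases paused RNA polymerase II into elongation, and SMAP-2 is a small-molecule activator of the protein phosphatase PP2A. No library was made from cells given 1 of the compounds alone, so a change reported here belongs to the combination. The 4 groups held 3 libraries each, 1 per donor, with total counts (donors 1, 2 and 3) of 4560123, 6345322 and 1762895 for resting DMSO cells, 2364266, 3906758 and 1458074 for resting treated cells, 7460501, 8318645 and 2138827 for activated DMSO cells and 9071432, 3994708 and 1345916 for activated treated cells. In a principal component analysis of log2 CPM, the first component held 66.4% of the variance and separated activated from resting libraries, the second held 9.56% and separated treated from DMSO libraries of resting cells, and the third held 8.77% and set the libraries of donor 3, the shallowest in each group, apart from the others. Values written after a gene are log2 fold changes ± SE from the edgeR fit, 3 donors per group, and CPM values, scaled by TMM over the tested genes, are means ± SD over 3 libraries. A gene is said to have risen, fallen or changed only where its Benjamini-Hochberg adjusted p in the edgeR quasi-likelihood test was under 0.05.

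The comparison of treated with DMSO libraries of resting cells asked what the combination did to unstimulated T cells of the same donors. HEXIM1, which holds CDK9 and cyclin T in an inactive complex, fell from 34.7 ± 8.46 to 4.63 ± 2.73 CPM (-2.87 ± 0.26, edgeR adjusted p = 1.53e-06). MYC, a transcription factor of growing cells, fell from 74.1 ± 1.51 to 23.5 ± 4.22 CPM (-1.64 ± 0.15, edgeR adjusted p = 1.53e-06). MGAM, the starch-digesting enzyme maltase-glucoamylase, rose from 0.291 ± 0.347 to 29 ± 4.72 CPM (6.15 ± 0.51, edgeR adjusted p = 7.42e-07). MAEA, a subunit of the CTLH ubiquitin ligase, rose from 42.2 ± 3.71 to 279 ± 34.4 CPM (2.71 ± 0.15, edgeR adjusted p = 1.36e-08). These 4 changes had the same direction in 3 of 3 donors. Among genes with a mean of at least 10 CPM, the largest rises after MGAM were SDCBP2 (4.13), EPHX1 (3.84), LGR4 (3.67), STARD4-AS1 (3.46), NAMA (3.14), CCDC17 (2.89) and H2BC4 (2.77). MAEA, CCNY-AS1 (2.68), PXDNL (2.65) and SLC13A3 (2.51) followed. EPHX1 encodes microsomal epoxide hydrolase, LGR4 a receptor for R-spondins, H2BC4 a histone H2B and SLC13A3 a dicarboxylate transporter. SPP1, which encodes the secreted protein osteopontin, fell most of such genes (-3.70 ± 0.73). Its call ended without the donor block (edgeR adjusted p = 0.103) and with DESeq2 (adjusted p = 0.0531, range over all settings and tools 5.02e-52 to 0.103), and without donor 3 its value was -8.73. After HEXIM1 came ZNF683 (-2.80), IATPR (-2.77), CXCR3 (-2.73), HNRNPA1L3 (-2.45) and RGL4 (-2.40). They were followed by LHPP (-2.39), THOC6 (-2.29), PARP11-AS1 (-2.25), SPON1 (-2.19) and UQCC2 (-2.16). ZNF683 encodes Hobit, a transcription factor of tissue-resident lymphocytes, and CXCR3 a chemokine receptor of type 1 helper cells. THOC6 belongs to the mRNA export complex THO and UQCC2 assembles respiratory complex III. Each of these genes moved in the same direction in 3 of 3 donors, with SEs of 0.15 to 0.73 and a highest edgeR adjusted p of 0.00119, for SPP1. ZNF683 also lost its call without the block and with DESeq2.

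The targets of the drugs and markers of activation were read out in every comparison. CCNT1, the cyclin partner of CDK9, rose (0.78 ± 0.15), and IL2RA, the α chain of the interleukin-2 receptor, fell (-1.07 ± 0.27). The PP2A scaffold gene PPP2R1A (0.24 ± 0.12) and the proliferation marker MKI67 (0.68 ± 0.51) were not called. CDK9 itself was called higher (0.48 ± 0.16, edgeR adjusted p = 0.0286), as was MCL1, a survival factor of the BCL2 family (0.53 ± 0.13, edgeR adjusted p = 0.00543), both in 3 of 3 donors. With library size alone they were at 0.17 and 0.23, and the adjusted p of CDK9 ran over 0.0192 to 0.521 and that of MCL1 over 4.06e-04 to 0.231 in all settings and tools. Without donor 1 or donor 2 CDK9 and IL2RA lost their call. Without donor 3 CDK9 and MCL1 lost their call. Without the block MCL1 lost its call. CDK9 and MCL1 lost their call with library size alone. CDK9 was not called by DESeq2, nor CDK9 and IL2RA when libraries were thinned, nor CDK9 and MCL1 with no filter, nor CDK9 with upper-quartile scaling. The catalytic PP2A gene PPP2CA is listed at 0 in all 12 libraries, where other gene models cover its whole span on the same strand.

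**Figure D1:**
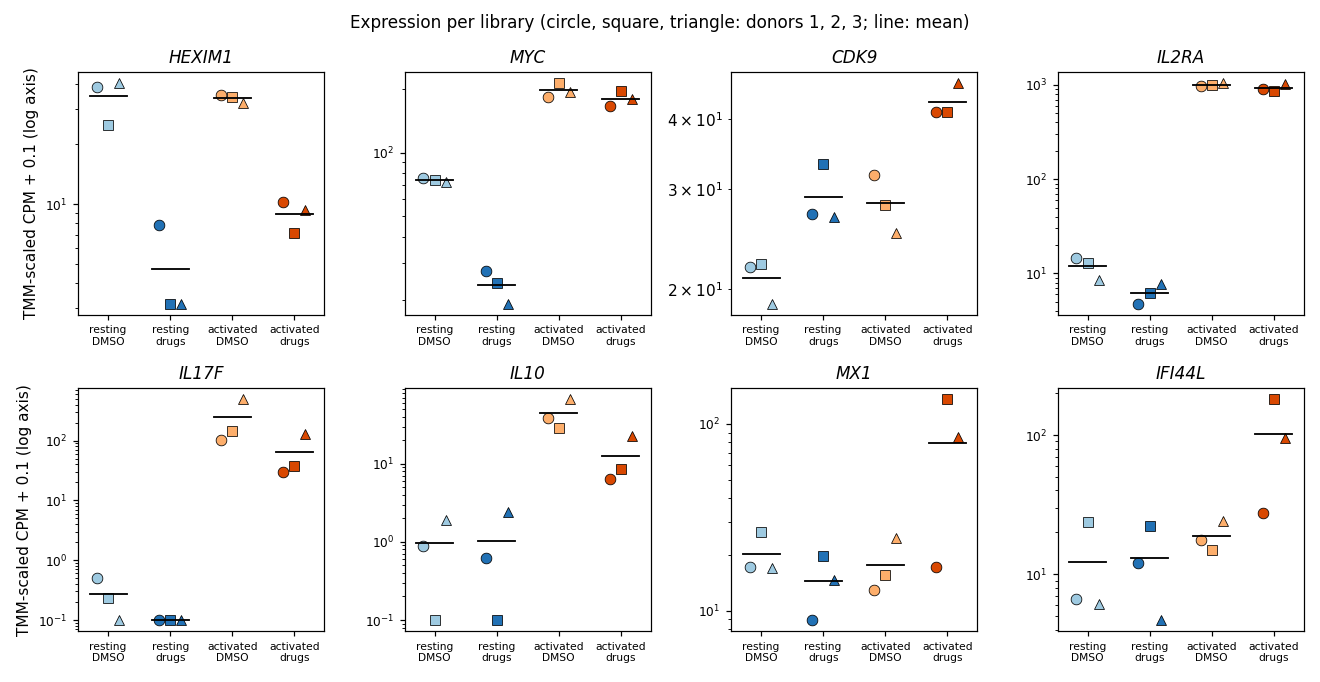
TMM-scaled CPM (log axis, 0.1 added) of HEXIM1, MYC, CDK9, IL2RA, IL17F, IL10, MX1 and IFI44L in each of the 12 libraries, by group, with 1 point per donor and a line at the group mean. HEXIM1 had a mean of 34.7 CPM in resting DMSO libraries and 4.63 in resting treated libraries, and IFI44L rose from a mean of 18.8 to 101 CPM with the drugs in activated cells.

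Positions in the deposited table (GRCh38) give each gene's whole span. HEXIM1 is at 45148475 to 45152099 on the plus strand of chromosome 17 (ENSG00000186834). MYC is at 127735434 to 127742951 on the plus strand of chromosome 8 (ENSG00000136997). CDK9 is at 127785679 to 127790792 on the plus strand of chromosome 9 (ENSG00000136807). IL10 is at 206767602 to 206774541 on the minus strand of chromosome 1 (ENSG00000136634). IFI44L is at 78619902 to 78646145 on the plus strand of chromosome 1 (ENSG00000137959).

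In resting cells 4122 of 12918 tested genes changed, 1984 up and 2138 down (edgeR quasi-likelihood test, adjusted p under 0.05). At least 2-fold changes numbered 1625, 562 up and 1063 down, and 4015 of the called genes moved in the same direction in 3 of 3 donors. Genes of the mitochondrial genome rose together: 11 of 13 tested members rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.64. MT-CO1, of cytochrome c oxidase, rose from 2166 ± 472 to 4501 ± 192 CPM (1.05 ± 0.21), and so did MT-ND4L (1.03) and MT-ND5 (0.86) of respiratory complex I. The mitochondrial list had camera adjusted p = 7.18e-07, and adjusted p = 0.695 with an estimated correlation. Without donors 1, 2 and 3 its members that rose numbered 5, 6 and 7. Of the cytosolic ribosomal protein genes, 18 of 72 tested members rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.45. Examples were RPL35 (0.91), RPL37 (0.80) and RPL36 (0.66), and RPL14 fell (-0.73). Ribosomal proteins had camera adjusted p = 3.77e-05, and adjusted p = 0.971 with an estimated correlation. Without donor 1, 3 of them rose and 1 fell. Without donor 2, edgeR called 0 higher and 1 lower (12 and 1 at an unadjusted p under 0.05), with a median of 0.40, and without the donor block 8 and 1. Of cytokine and chemokine genes, 0 of 31 tested members rose and 5 fell (0 and 5 adjusted over the list alone). The share falling was like that of all genes. Their median was -0.62, or -0.36 with the 7 members that had 0 counts in a group set at their floor. LTB, which encodes lymphotoxin β, fell from 1114 ± 265 to 297 ± 50.0 CPM (-1.88 ± 0.16), and CCL5, a chemokine of memory T cells, from 482 ± 212 to 151 ± 75 CPM (-1.65 ± 0.21). The cytokine list, those 7 included, had camera adjusted p = 0.0284 (0.695 with an estimated correlation), which does not show a general fall. In the same libraries NK and CD8+ markers, whose cells also make CCL5, went from 607 ± 469 to 394 ± 261 CPM in sum. Of the genes of naive and quiescent T cells, 2 of 33 tested members rose and 13 fell (2 and 13 adjusted over the list alone), with a median of -0.24. KLF2, a transcription factor of quiescent T cells, fell from 437 ± 64.9 to 248 ± 54.2 CPM (-0.82 ± 0.15), and DGKA, a lipid kinase, fell too (-0.83). Naive genes had camera adjusted p = 0.0274, and adjusted p = 0.695 with an estimated correlation. Without the block 2 rose and 8 fell. Of Integrator, which cleaves transcripts of paused polymerase and can carry PP2A, 0 of 16 tested members rose and 5 fell (0 and 5 adjusted over the list alone), with a median of -0.33. INTS3 (-1.98), NABP1 (-1.42), INTS7 (-2.12) and INTS6 (-0.86) fell. Integrator had camera adjusted p = 0.0284, and adjusted p = 0.695 with an estimated correlation. SEs in this group of genes were 0.13 to 0.28 and their highest edgeR adjusted p was 0.0143, for RPL36. Without donor 1 RPL36 lost its call. Without donor 2 RPL35, RPL36 and RPL37 lost their call.

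No list was called by camera with an estimated correlation (0 of 35, 2 at an unadjusted p under 0.05), while fry, which asks whether a list moves on balance 1 way, called 11. Scaling moved the balance of calls. With library size alone the median of all genes went from -0.02 to -0.33 and the share of called genes that rose from 48.1% to 16.5%, and with no count filter they came to -0.19 and 28.6%. Without donor 1 the test called 2069 genes and 1869 without donor 2.

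The other lists were not called by camera in resting cells, and members of many moved both ways. In the RNA polymerase II elongation list, 12 of 39 tested members rose and 6 fell (13 and 7 adjusted over the list alone, 4 and 13 with library size alone with a median of -0.21, not 0.10). After HEXIM1, POLR2A, the largest polymerase subunit, fell (-0.92), and NELFA (0.84) and CCNT2 (0.90) rose. In the list of PP2A subunits and regulators, 7 of 23 tested members rose and 2 fell (7 and 2 adjusted over the list alone, 1 and 5 with library size alone with a median of -0.14, not 0.16). They included ARPP19, a PP2A inhibitor (0.97), and PPP2R2A (0.63) and STRN3 (0.63). Of the immediate early genes, 7 of 40 tested members rose and 9 fell (7 and 9 adjusted over the list alone). After MYC came JUND, which fell (-1.35), and KLF6 (1.14) and CCNL1 (0.98). Among anti-apoptotic genes 4 of 9 tested members rose and 0 fell (5 and 0 adjusted over the list alone, 2 and 3 with library size alone), led by BIRC2 (1.31) and XIAP (0.92). Among pro-apoptotic genes 1 of 18 tested members rose and 6 fell (2 and 6 adjusted over the list alone), with BBC3 (-1.45), BCL2L11 (-0.97) and CASP9 (-1.22) lower. Of p53 targets, 4 of 28 tested members rose and 5 fell (6 and 5 adjusted over the list alone, 6 and 4 with median-ratio scaling, 1 and 9 with library size alone with a median of -0.11, not 0.20), AEN being the first by p (1.48). Among activation receptors and transcription factors 5 of 37 tested members rose and 10 fell (6 and 10 adjusted over the list alone). HAVCR2, the inhibitory receptor TIM-3, and SLC3A2, an amino acid transporter chain, rose (2.14 and 0.84), and TIGIT fell (-1.15). In the T cell receptor signalling list, 3 of 33 tested members rose and 11 fell (3 and 12 adjusted over the list alone), among them THEMIS (-0.76), LCK (-0.77) and CD4 (-0.75). Among helper subset and regulatory T cell genes 0 of 17 tested members rose and 6 fell (0 and 6 adjusted over the list alone). After CXCR3, TBX21 (-1.2) and IKZF2 (-1.02) fell, which encode transcription factors of type 1 and regulatory cells. Among S phase genes 2 of 37 tested members rose and 7 fell (2 and 7 adjusted over the list alone), with MCM3 (-1.02) and PCNA (-0.91) lower. G2/M genes gave 2 and 2 of 40 (1 and 1 adjusted over the list alone, 1 and 6 with library size alone with a median of -0.02, not 0.29) up and down. Among histone genes with polyadenylated transcripts 3 of 13 tested members rose and 1 fell (3 and 1 adjusted over the list alone, 3 and 3 with library size alone with a median of -0.04, not 0.25). H2BC12 (2.19) and H2BC21 (1.80) rose beside H2BC4, and as near-identical copies their split of reads is uncertain. Of endoplasmic reticulum stress genes 2 of 32 tested members rose and 10 fell (2 and 10 adjusted over the list alone), with ATF4 (0.90) higher and AARS1 (-0.94) and CALR (-0.90) lower. Of heat shock genes 1 of 18 tested members rose and 4 fell (1 and 3 adjusted over the list alone). Interferon-stimulated genes split 4 and 3 of 42 (2 and 3 adjusted over the list alone, 2 and 5 with upper-quartile scaling, 1 and 9 with library size alone), with ISG20 (-1.41) and MX2 (-1.5) lower and PARP9 (0.78) higher. Without donor 1 the interferon list had 0 up and 7 down. NF-κB targets split 9 and 7 of 36 (9 and 7 adjusted over the list alone, 6 and 7 with upper-quartile scaling, 1 and 11 with library size alone with a median of -0.14, not 0.17). Among these genes SEs were 0.12 to 0.37 and their highest edgeR adjusted p was 0.00560, for IKZF2. Without donor 1 CASP9, IKZF2 and PARP9 lost their call. Without donor 2 STRN3 lost its call. Without the block MX2 lost its call. PARP9, PPP2R2A and STRN3 lost their call with library size alone. CASP9 and STRN3 were not called when libraries were thinned, nor STRN3 with no filter.

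Up and down counts in the remaining lists for the drugs in resting cells were 2 and 3 of 26 (2 and 2 adjusted over the list alone) for homologous recombination and checkpoints. They were 4 and 4 of 39 (3 and 4 adjusted over the list alone, 1 and 11 with library size alone with a median of -0.18, not 0.12) for ribosome biogenesis and 5 and 2 of 36 (5 and 0 adjusted over the list alone, 1 and 7 with library size alone with a median of -0.11, not 0.19) for nuclear genes of oxidative phosphorylation. Glycolysis had 0 and 3 of 20 (0 and 1 adjusted over the list alone), cholesterol synthesis 4 and 3 of 22 (4 and 3 adjusted over the list alone, 2 and 5 with library size alone with a median of -0.26, not 0.06) and lysosome and autophagy 7 and 3 of 33 (7 and 3 adjusted over the list alone, 7 and 4 with upper-quartile scaling with a median of -0.02, not 0.03, 4 and 4 with library size alone with a median of -0.24, not 0.03). Nuclear long non-coding RNAs and snoRNA hosts had 4 and 2 of 17 (4 and 3 adjusted over the list alone, 1 and 4 with library size alone with a median of -0.12, not 0.17). HIV host factors had 5 and 7 of 24 (6 and 7 adjusted over the list alone), with XPO1, of nuclear export, and NUP153, of the nuclear pore, up (1.08 and 1.07). The median (-0.22) and mean (-0.14) of this list were negative while its camera direction was up (adjusted p = 0.935, not called). Markers of other blood cells, summed per list in DMSO and treated resting cells, were at 474 ± 622 and 357 ± 458 CPM for monocytes. They were at 565 ± 644 and 805 ± 964 CPM for B cells. Donors 1, 2 and 3 had 103, 127 and 1193 CPM of monocyte, 1081, 594 and 144 of NK and CD8+ and 395, 1276 and 22.3 of B cell markers with DMSO. Of the monocyte markers, 0 of 12 tested members rose and 3 fell (0 and 3 adjusted over the list alone), with FCGR3A (-1.94), S100A9 (-1.41) and LYZ (-0.89) lower and CD14 (-0.95) not called. NK and CD8+ markers gave 0 and 3 of 15 (0 and 3 adjusted over the list alone) up and down, with GZMK (-2.07) and GNLY (-0.76) lower. Platelet markers gave 0 and 1 of 4 (0 and 1 adjusted over the list alone), namely CLU (-1.62). edgeR called 0 members of the B cell, erythroid and dendritic lists (2, 0 and 0 at an unadjusted p under 0.05). Without donor 1 GNLY lost its call. Without donor 2 FCGR3A and LYZ lost their call. Without donor 3 LYZ lost its call. Without the block GNLY, LYZ and S100A9 lost their call. LYZ and S100A9 were not called by DESeq2, nor S100A9 by limma-voom.

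The same comparison in activated cells asked what the combination did to stimulated T cells of the same donors. Of 42 tested interferon-stimulated genes, many of which block viruses, 21 rose, and of 31 cytokine and chemokine genes 9 fell (camera adjusted p = 0.281 and 0.178 with an estimated correlation). Without donor 2 or the donor block edgeR called 0 of the former (18 and 32 rose at an unadjusted p under 0.05). IFI44L, induced by interferon, rose from 18.8 ± 4.71 to 101 ± 77.2 CPM (2.13 ± 0.40, edgeR adjusted p = 0.00786). MX1, an antiviral GTPase, rose from 17.5 ± 6.15 to 79.1 ± 59.5 CPM (1.94 ± 0.36, edgeR adjusted p = 0.00787). IL10, an anti-inflammatory cytokine, fell from 44.7 ± 20.1 to 12.4 ± 8.67 CPM (-2.06 ± 0.26, edgeR adjusted p = 4.09e-04). IL17F, of type 17 cells, fell from 247 ± 216 to 65.2 ± 55.0 CPM (-1.89 ± 0.13, edgeR adjusted p = 5.93e-06). HEXIM1 fell from 33.9 ± 1.5 to 8.82 ± 1.57 CPM (-1.97 ± 0.20, edgeR adjusted p = 7.59e-05). These 5 changes had the same direction in 3 of 3 donors. In order of size, among genes with a mean of at least 10 CPM, the rises were IFIT2 (2.38), RSAD2 (2.32), IFI44L, IFIT3 (2.07), MX1 and CCDC200 (1.89). Then came IFI44 (1.87), ACTA2 (1.75), TP53I3 (1.73), SLFN5 (1.58), TMEM140 (1.54) and MX2 (1.51). RSAD2 encodes the antiviral enzyme viperin, MX2 a GTPase that restricts HIV, ACTA2 a smooth muscle actin and TP53I3 a p53-induced oxidoreductase. The falls of such genes, after IL10, HEXIM1 and IL17F, were CCL17 (-1.83), IL26 (-1.62), GZMB (-1.57), EPAS1 (-1.54) and LIF (-1.52). Then came UST-AS2 (-1.43), CXCL10 (-1.34), ADI1 (-1.26) and OSM (-1.23). CCL17 and CXCL10 encode chemokines, IL26, LIF and OSM cytokines, GZMB the cytotoxic protease granzyme B and EPAS1 the hypoxia factor HIF-2α. Each of these genes moved in the same direction in 3 of 3 donors, with SEs of 0.13 to 0.48 and a highest edgeR adjusted p of 0.0335, for CXCL10. Without donor 1 CXCL10, EPAS1 and UST-AS2 lost their call. Without donor 2 all genes named as changed but ACTA2, ADI1, CCDC200, HEXIM1, IL10, IL17F, LIF and OSM lost their call. Without donor 3 IFIT3 lost its call. Without the block all genes named as changed but ACTA2, ADI1, HEXIM1, LIF, OSM, SLFN5 and TMEM140 lost their call. CCL17, CXCL10, GZMB, IFI44L, IFIT3 and RSAD2 were not called by DESeq2, nor CXCL10 by limma-voom, nor MX2 and UST-AS2 when libraries were thinned. The log2 changes without donor 2 were 1.10 for IFIT2, 1.04 for RSAD2, 1.28 for IFI44L, 0.96 for IFIT3, 1.10 for MX1, 1.03 for IFI44 and 0.53 for MX2. Without donor 1 that of IFIT3 was 3.30.

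Of the targets and activation markers in activated cells, CDK9 rose (0.55 ± 0.14, edgeR adjusted p = 0.0330, 3 of 3 donors, range of adjusted p over all settings and tools 0.010 to 0.345). CDK9 was not called with any 1 donor left out, without the block, with library size alone, by DESeq2, when libraries were thinned and with no filter. Not called were CCNT1 (0.55), MYC (-0.13), MCL1 (0.35), PPP2R1A (-0.14), IL2RA (-0.12) and MKI67 (-0.32).

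In activated cells 462 of 12918 tested genes changed, 285 up and 177 down (edgeR quasi-likelihood test, adjusted p under 0.05). At least 2-fold changes numbered 192, 161 up and 31 down. The test called 13 genes without donor 2, 187 without donor 1, 265 without donor 3 and 64 without the donor block. The share of called genes that rose was 61.7%, or 30.8% without donor 2, 74.3% without donor 1 and 81.3% without the block. In the interferon-stimulated list 21 of 42 tested members rose and 0 fell (35 and 0 adjusted over the list alone), with a median of 1.02. IFIT1, an RNA-binding antiviral protein, rose by 3.72 ± 0.59 and OAS3, an RNA sensor, by 1.34 ± 0.25. Without donor 2 they were at 1.87 and 0.89, not called. The interferon list had camera adjusted p = 7.61e-28, and adjusted p = 0.281 with an estimated correlation. Without donor 2 the median was 0.53 and without the block 1.08. Without donor 1, 31 rose and without donor 3, 11. In the cytokine and chemokine list, 0 of 31 tested members rose and 9 fell (0 and 10 adjusted over the list alone), with a median of -0.15. IL5, a cytokine of type 2 cells, was among them (-1.07). The cytokine list had camera adjusted p = 1.37e-10, and adjusted p = 0.178 with an estimated correlation. Without the block 1 member fell, and without donor 1 or donor 2, 4 fell. Of the G2/M genes, 0 of 40 tested members rose and 8 fell (0 and 20 adjusted over the list alone), with a median of -0.35. CCNA2 (-0.71), PLK1 (-0.77), CDC20 (-0.47) and TOP2A (-0.55), which drive mitosis, fell. G2/M genes had camera adjusted p = 8.37e-13, and adjusted p = 0.324 with an estimated correlation. Fewer G2/M genes were called with upper-quartile scaling (4), library size alone (3), without donor 1 (1) and without donor 3 (2). Without donor 2 or the block edgeR called 0 (9 and 13 fell at an unadjusted p under 0.05). Of the ribosome biogenesis genes, many of them MYC targets, 0 of 39 tested members rose and 4 fell (0 and 4 adjusted over the list alone), with a median of -0.23. ODC1 (-0.91), DKC1 (-0.52), NPM1 (-0.58) and NOP56 (-0.48) fell. Ribosome biogenesis had camera adjusted p = 3.71e-08, and adjusted p = 0.281 with an estimated correlation. Without donor 1, 2 of them fell, without donor 3, 1, and without donor 2 or the block edgeR called 0 (4 and 9 at an unadjusted p under 0.05). With an estimated correlation camera called 0 of 35 lists (5 at an unadjusted p under 0.05), and fry called 5. Without donor 1 CDC20, NOP56, NPM1, PLK1 and TOP2A lost their call. Without donor 2 all genes named as changed but IL5 lost their call. Without donor 3 CDC20, DKC1, NOP56, NPM1 and TOP2A lost their call. Without the block all genes named as changed lost their call. CDC20, DKC1, NOP56 and TOP2A lost their call with library size alone. CDC20 and TOP2A were not called by DESeq2, nor CDC20 by limma-voom, nor CDC20, DKC1, NOP56, NPM1, PLK1 and TOP2A when libraries were thinned.

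**Figure D2:**
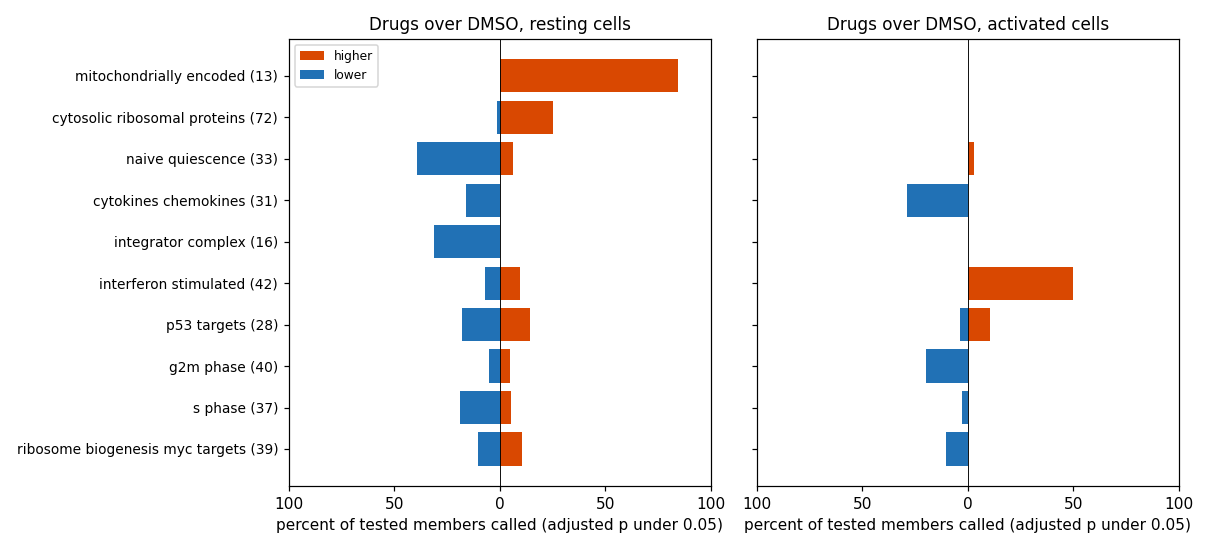
Percent of the tested members of 10 fixed gene lists that were called higher (bars to the right) or lower (bars to the left) with the drugs in resting and in activated cells. In resting cells 11 of 13 genes of the mitochondrial genome rose, and in activated cells 21 of 42 interferon-stimulated genes rose, while in resting cells the balance of calls turned with median-ratio scaling for p53 targets and with upper-quartile scaling or library size alone for interferon-stimulated genes, and G2/M and ribosome biogenesis genes had negative medians with library size alone.

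Further lists were called in activated cells. Of p53 targets, 3 of 28 tested members rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.21. Beside TP53I3, PMAIP1, a death factor, and CDKN1A, a cell cycle inhibitor, rose (0.80 and 0.69), and MDM2, which degrades p53, fell (-0.49). The p53 list had camera adjusted p = 5.92e-04, and adjusted p = 0.410 with an estimated correlation. Of the elongation list, 1 of 39 tested members rose and 3 fell (3 and 6 adjusted over the list alone), with a median of -0.10, or 0.01 without donor 2. After HEXIM1, POLR2A (-0.70) and NELFCD (-0.48) fell. The elongation list had camera adjusted p = 0.0496, and adjusted p = 0.410 with an estimated correlation. Of immediate early genes 1 of 40 tested members rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.13. The called member was PPP1R15A, a phosphatase subunit of the stress response (0.93). Immediate early genes had camera adjusted p = 0.0422, and adjusted p = 0.607 with an estimated correlation. Of S phase genes 0 of 37 tested members rose and 1 fell (0 and 1 adjusted over the list alone), namely RRM2 of ribonucleotide reductase (-0.85), with a list median of -0.21. S phase genes had camera adjusted p = 5.92e-04, and adjusted p = 0.504 with an estimated correlation. Of HIV host factors, 2 of 24 tested members rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.17. BST2, which tethers virions to the cell (0.68), and MX2 rose, and both are also in the interferon list. HIV host factors had camera adjusted p = 0.0496, and adjusted p = 0.281 with an estimated correlation. Of helper subset genes, 0 of 17 tested members rose and 1 fell (0 and 1 adjusted over the list alone), namely CTLA4, an inhibitory receptor (-0.79), with a list median of -0.20. Helper subset genes had camera adjusted p = 0.0289, and adjusted p = 0.281 with an estimated correlation. The mitochondrially encoded list had a median of 0.19, and edgeR called 0 of its 13 members (2 at an unadjusted p under 0.05). That list had camera adjusted p = 0.0496, and adjusted p = 0.607 with an estimated correlation. Activation receptors and transcription factors were not called as a list (camera adjusted p = 0.104), and 0 of 37 tested members rose and 6 fell (0 and 7 adjusted over the list alone). BATF3, a transcription factor, TNFRSF8, the receptor CD30, and TFRC, the transferrin receptor, fell (-0.76, -0.89 and -0.59). SEs spanned 0.12 to 0.21 and their highest edgeR adjusted p was 0.0472, for NELFCD. Without donor 1 CDKN1A, MDM2 and NELFCD lost their call. Without donor 2 or the block all genes named as changed but HEXIM1 lost their call. Without donor 3 BST2, CDKN1A, CTLA4, MDM2, PMAIP1, PPP1R15A and TFRC lost their call. MDM2, NELFCD and TFRC lost their call with library size alone. BATF3, CDKN1A, CTLA4, NELFCD and PMAIP1 were not called by DESeq2, nor CDKN1A, MDM2, MX2 and NELFCD when libraries were thinned. Nor was CDKN1A with median-ratio scaling, or NELFCD with the stricter filter, upper-quartile scaling or overlapping genes left out. Without donor 2 the values of PMAIP1, NELFCD and TNFRSF8 were 0.37, -0.30 and -0.59.

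Single members moved in other lists of activated cells. CD3G (-0.65) and LCK (-0.52) of T cell receptor signalling, LDHA, lactate dehydrogenase A (-0.64), and the histone gene H2AX (-0.94) fell. TNFRSF10A, a death receptor (0.78), SQSTM1, an autophagy receptor (0.76), SLFN5 of the naive list and IGHD of the B cell list (1.11) rose. Up and down counts were 0 and 2 of 33 (0 and 2 adjusted over the list alone) for T cell receptor signalling and 2 and 0 of 18 (2 and 1 adjusted over the list alone) for pro-apoptotic genes. Glycolysis had 0 and 1 of 20 (0 and 1 adjusted over the list alone), naive genes 1 and 0 of 33 (6 and 1 adjusted over the list alone) and endoplasmic reticulum stress 1 and 0 of 32 (1 and 0 adjusted over the list alone, 1 and 0 with median-ratio scaling with a median of -0.01, not 0.02). Lysosome and autophagy had 1 and 0 of 33 (1 and 0 adjusted over the list alone), histone genes 0 and 1 of 13 (1 and 2 adjusted over the list alone) and B cell markers 1 and 0 of 14 (1 and 0 adjusted over the list alone). In the other 15 lists edgeR called 0 members. At an unadjusted p under 0.05 stood 5 of 23 PP2A, 3 of 16 Integrator, 1 of 9 anti-apoptotic, 4 of 26 homologous recombination, 0 of 72 ribosomal protein, 2 of 36 nuclear oxidative phosphorylation and 0 of 22 cholesterol synthesis genes, and 2 of 36 NF-κB target, 2 of 18 heat shock, 4 of 17 nuclear long non-coding RNA, 1 of 12 monocyte, 2 of 15 NK and CD8+, 0 of 4 platelet, 1 of 4 erythroid and 1 of 3 dendritic genes. Summed markers in DMSO and treated activated cells were at 30.7 ± 9.90 and 38.9 ± 5.61 CPM for monocytes and 299 ± 179 and 329.8 ± 177 CPM for NK and CD8+ cells. For B cells they were at 371 ± 352 and 411 ± 373 CPM and for dendritic cells at 15.5 ± 6.13 and 16.9 ± 4.84 CPM. Without donor 1 CD3G, IGHD, LCK and TNFRSF10A lost their call. Without donor 2 all genes named as changed lost their call. Without donor 3 LDHA lost its call. Without the block all genes named as changed but SLFN5 lost their call. LCK lost its call with library size alone. IGHD was not called by DESeq2, nor CD3G, IGHD, LCK and TNFRSF10A when libraries were thinned.

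Whether the drugs acted differently in the 2 states was tested as an interaction, the log2 change in activated cells minus that in resting cells. The antiviral gene MX2 fell in resting cells (-1.5, not called without the donor block) and rose in activated cells (1.51, not called without donor 2, without the block or in thinned libraries), a difference of 3.02 ± 0.52 (edgeR adjusted p = 0.00236). MX1 differed by 2.56 ± 0.58 (edgeR adjusted p = 0.0110). MYC fell in resting cells (-1.64) and was at -0.13 in activated cells, a difference of 1.51 ± 0.19 (edgeR adjusted p = 3.82e-04). MAEA rose from 42.2 to 279 CPM in resting cells and stood at 43.7 ± 3.27 and 51.5 ± 11.2 CPM in activated cells, a difference of -2.53 ± 0.21 (edgeR adjusted p = 9.23e-06). These 4 differences had the same sign in 3 of 3 donors. Among genes with a mean of at least 10 CPM, the most positive differences were CCNE1, the G1/S cyclin E1 (3.02), MX2, OAS1 (2.84), IFI6 (2.71), MX1, DPEP2 (2.54), ISG15 (2.46) and HELZ2 (2.38). The most negative of such genes were MTFR2, a regulator of mitochondrial fission (-3.60), HAVCR2 (-2.60), MAEA, GCNA (-2.24), CENPA (-2.17), COQ3 (-2.00), STARD4-AS1 (-1.98) and MAFK (-1.94). The mean of 10 CPM was taken over all 12 libraries, so a gene could pass it through its activated libraries alone. OAS1, IFI6 and ISG15 are induced by interferon, CENPA is the histone of centromeres and COQ3 an enzyme of ubiquinone synthesis. The SEs of the differences were 0.19 to 0.81, and the highest edgeR adjusted p was 0.0247, for CCNE1. Without donor 1 CCNE1, COQ3 and STARD4-AS1 lost their call. Without donor 2 all genes named as changed but COQ3, GCNA, HAVCR2, MAEA, MAFK, MTFR2 and MYC lost their call. Without donor 3 CCNE1, ISG15, OAS1 and STARD4-AS1 lost their call. Without the block CCNE1, HELZ2, MX1 and OAS1 lost their call. STARD4-AS1 lost its call with library size alone. CCNE1, DPEP2 and STARD4-AS1 were not called when libraries were thinned. Without donor 2 MX2 and OAS1 were at 1.82 and 1.67.

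HEXIM1 was not called for the interaction (0.89 ± 0.36, edgeR adjusted p = 0.114), and was called with library size alone and with a block per donor and state (range of adjusted p over all settings and tools 0.0193 to 0.293). Nor were IL2RA (0.94), MKI67 (-1.0), CDK9 (0.07), CCNT1 (-0.23), MCL1 (-0.18) and PPP2R1A (-0.39). The interaction was called for 1408 of 12918 genes, 792 positive and 616 negative (edgeR quasi-likelihood test, adjusted p under 0.05). At least 2-fold differences numbered 769, 591 positive and 178 negative. With library size alone the median of all genes went from 0.05 to 0.41 and the positive share of called genes from 56.3% to 93.3%. Upper-quartile scaling gave 0.14 and 70.0%, no count filter 0.18 and 78.5%, and DESeq2 0.01 and 43.8%. The test called 296 genes without donor 1, 145 without donor 2 and 573 without the donor block.

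Interferon-stimulated genes differed between the states: 13 of 42 were more positive in activated cells and 0 more negative (26 and 0 adjusted over the list alone), with a median of 1.31. The interferon list had camera adjusted p = 1.88e-09, and adjusted p = 0.562 with an estimated correlation. Without donors 1, 2 and 3 the count was 26, 1 and 8, without the block 4 and with library size alone 28. ISG20, MX2, OAS2 and IFIT1 had the smallest p (2.21, 3.02, 1.53 and 4.34), and without donor 2 IFIT1 was at 2.42. Naive genes were more positive and more negative in 7 and 0 of 33 (12 and 2 adjusted over the list alone), with a median of 0.35 and DGKA (1.02) and SLFN5 (1.28) among the positive ones. The naive list had camera adjusted p = 5.62e-04, and adjusted p = 0.562 with an estimated correlation. Without donor 2, 1 was called and without the block 3. Endoplasmic reticulum stress genes gave 6 and 1 of 32 (7 and 1 adjusted over the list alone), with ATF4 (-1.10) negative and AARS1 (1.02) and SDF2L1 (0.94) positive. Their list had camera adjusted p = 0.0211, and adjusted p = 0.562 with an estimated correlation. Of mitochondrially encoded genes 0 were positive and 2 of 13 negative (0 and 4 adjusted over the list alone), namely MT-ND4L (-0.73) and MT-CO2 (-0.82), and without donor 1, donor 2 or the block edgeR called 0 (2, 3 and 6 at an unadjusted p under 0.05). That list had camera adjusted p = 4.17e-05, and adjusted p = 0.562 with an estimated correlation. Positive and negative counts were 0 and 1 of 72 (0 and 0 adjusted over the list alone, 3 and 0 with library size alone) for ribosomal proteins, with RPL4 (-0.76). Ribosomal proteins had camera adjusted p = 2.88e-06, and adjusted p = 0.835 with an estimated correlation. Ribosome biogenesis had 0 and 3 of 39 (0 and 2 adjusted over the list alone, 0 and 2 with library size alone with a median of 0.04, not -0.29), with NOP58 (-1.10) and DDX21 (-0.90). Ribosome biogenesis genes had camera adjusted p = 0.00198, and adjusted p = 0.562 with an estimated correlation. The elongation list had 0 and 4 of 39 (0 and 6 adjusted over the list alone, 2 and 0 with library size alone with a median of 0.20, not -0.15), with NELFA (-0.94) and SUPT5H (-0.77). Elongation factors had camera adjusted p = 0.0241, and adjusted p = 0.562 with an estimated correlation. PP2A subunits and regulators had 0 and 3 of 23 (0 and 3 adjusted over the list alone, 2 and 1 with library size alone), with ARPP19 (-0.90), PPP2R3C (-0.88) and PPP2R2A (-0.72). The PP2A list had camera adjusted p = 0.0106, and adjusted p = 0.562 with an estimated correlation. Nuclear oxidative phosphorylation had 0 and 3 of 36 (0 and 3 adjusted over the list alone, 0 and 0 with library size alone with a median of 0.06, not -0.25). These nuclear genes had camera adjusted p = 0.00848, and adjusted p = 0.835 with an estimated correlation. G2/M genes had 0 and 3 of 40 (0 and 2 adjusted over the list alone), with PLK1 (-1.93) and CCNA2 (-1.72) after CENPA, CCNA2 being at -0.71 without donor 2. The G2/M list had camera adjusted p = 0.0406, and adjusted p = 0.835 with an estimated correlation. Histone genes had 0 and 2 of 13 (0 and 3 adjusted over the list alone), with H2BC12 (-1.60) and H2BC4 (-2.05). Histone genes had camera adjusted p = 0.00848, and adjusted p = 0.562 with an estimated correlation. Outside the called lists, LTB and CCL5, which fell in resting cells, differed by 1.81 and 1.80, and the Integrator genes INTS3 and INTS7 by 1.70 and 1.68. The SEs of the genes named here were 0.17 to 0.93 and their highest edgeR adjusted p was 0.0488, for CCNA2. Without donor 1 all genes named as changed but CCL5, CENPA, DGKA, H2BC12, IFIT1, INTS3, ISG20, LTB, MX2, NOP58, OAS2, SLFN5 and SUPT5H lost their call. Without donor 2 all genes named as changed but CCL5, H2BC12, INTS3, ISG20, LTB and PLK1 lost their call. Without donor 3 CCNA2, MT-CO2, PPP2R2A, RPL4, SDF2L1 and SUPT5H lost their call. Without the block CCL5, CCNA2, IFIT1, MT-CO2, MT-ND4L, NOP58, OAS2, RPL4, SDF2L1 and SUPT5H lost their call. CCNA2, MT-ND4L, NELFA, PPP2R2A, PPP2R3C, RPL4 and SUPT5H lost their call with library size alone. CCNA2, INTS7, MT-CO2, NELFA, PLK1, PPP2R2A and RPL4 were not called when libraries were thinned, nor CCNA2, PPP2R2A and SUPT5H with no filter. Nor was CCNA2 with the stricter filter, upper-quartile scaling, or mitochondrially encoded or overlapping genes left out. By camera with an estimated correlation 0 of 35 lists were called (0 at an unadjusted p under 0.05), and fry called 0 (13 at an unadjusted p under 0.05).

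**Figure D3:**
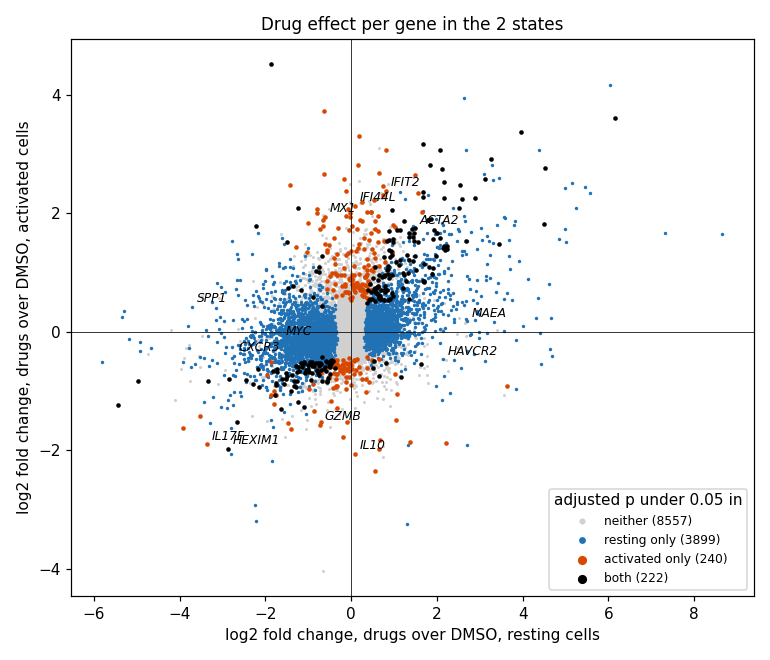
Log2 fold change with the drugs in resting cells (x axis) against activated cells (y axis), 1 point per tested gene, coloured by whether edgeR called the gene in both states, in resting cells alone or in activated cells alone. Across the 12918 genes Pearson r was 0.333, with 123 genes higher and 80 lower in both states.

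HEXIM1 and POLR2A fell with the drugs in both states, POLR2A in activated cells not without donor 2 or the donor block. Across the 12918 genes, which are not independent replicates, the log2 changes in the 2 states correlated with Pearson r = 0.333 and Spearman rho = 0.281 (covariance 0.131). In both states 123 genes rose, where independent lists would share 43.8, and 80 fell, against 29.3. Up in resting and down in activated cells were 6, against 27.2, and the other way 13, against 47.2. The comparisons shared donors but no libraries. Without donors 1, 2 and 3 the genes higher in both numbered 40, 3 and 64, and those lower in both 13, 3 and 39. Without the donor block they numbered 28 and 7, and with library size alone 77 were higher in both.

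Activated and resting DMSO libraries were compared to give the change on stimulation, which includes any change in other blood cells in the cultures. IL2RA, which marks activated T cells, rose from 11.9 ± 3.17 to 1007 ± 38.4 CPM (6.30 ± 0.20, edgeR adjusted p = 3.36e-13). IFNG, interferon γ, rose from 2.81 ± 1.51 to 1186 ± 509 CPM (8.82 ± 0.27, edgeR adjusted p = 3.36e-13), and MKI67 by 6.89 ± 0.23. KLF2 fell from 437 ± 64.9 to 12.2 ± 3.25 CPM (-5.25 ± 0.20, edgeR adjusted p = 1.10e-12). Each moved the same way in 3 of 3 donors. IL13 and IL22, cytokines of type 2 and type 17 cells, had 0 counts in resting DMSO libraries and were at least 513-fold and 92.5-fold higher in activated ones. The monocyte gene S100A8 had 0 counts in activated DMSO libraries and was at least 53.6-fold lower. The floor was 3 counts over the group. Among genes with a mean of at least 10 CPM, the other largest rises were IL9 (10.09), IL5 (9.95), IL17F (9.46), CXCL9 (9.09), CCL17 (8.90), IFNG, ZBED2 (8.61), KIF20A (7.85), LIF (7.84) and IL17A (7.79). KIF20A is a mitotic kinesin, and most of the others encode cytokines or chemokines. The other largest falls of such genes were NOG (-7.70), SPON1 (-7.58), S100A9 (-6.26), DPEP2 (-6.21), C16orf74 (-6.03), CD14 (-6.03), MYO16 (-5.36), KLF2, SNED1 (-5.18), AK5 (-5.04) and EPHA4 (-5.02). NOG encodes a BMP antagonist, CD14 and S100A9 are monocyte genes and EPHA4 an ephrin receptor. MYC (1.41), PPP2R1A (0.88) and CDK9 (0.44) rose, CCNT1 (-0.46) and MCL1 (-0.66) fell, and HEXIM1 was not called (0.04 ± 0.17). The adjusted p of CDK9 ran over 0.00719 to 0.507 in all settings and tools. CDK9 lost its call without donor 1, without donor 2 and with library size alone. CDK9 was not called when libraries were thinned, nor CCNT1 with no filter, nor CDK9 with upper-quartile scaling. SEs in this group of genes were 0.12 to 0.82, and the highest edgeR adjusted p among those that changed was 0.0114, for CDK9.

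Activation changed 9174 of 12918 genes, 4366 up and 4808 down (edgeR quasi-likelihood test, adjusted p under 0.05), 5688 of them at least 2-fold. With upper-quartile scaling or library size alone the median of all genes went from -0.10 to -0.27 or -0.20. G2/M genes had 40 up and 0 down of 40 (40 and 0 adjusted over the list alone, median 5.25), led by CDC20 (6.99), CDK1 (6.98) and CCNB1 (5.58). S phase genes had 37 up and 0 down of 37 (37 and 0 adjusted over the list alone, median 3.50), led by RRM2 (7.78), TK1 (6.80) and CDT1 (6.49). Homologous recombination genes had 22 up and 2 down of 26 (22 and 2 adjusted over the list alone, median 2.47), with CHEK1 (5.38) up and ATM (-3.32) down. Cytokine genes had 26 up and 2 down of 31 (26 and 2 adjusted over the list alone, median 5.06). Activation receptors and factors had 32 up and 3 down of 37 (32 and 3 adjusted over the list alone, median 2.43) and NF-κB targets 24 up and 4 down of 36 (24 and 4 adjusted over the list alone, median 0.89), with LTA (6.0), TNF (4.65), BATF3 (5.80) and IRF4 (4.67) among those higher. Ribosome biogenesis had 38 up and 0 down of 39 (38 and 0 adjusted over the list alone, median 2.05), with SRM (3.34) and NOP16 (3.32). Nuclear oxidative phosphorylation had 33 up and 2 down of 36 (33 and 2 adjusted over the list alone, median 1.22). Glycolysis had 14 up and 2 down of 20 (14 and 2 adjusted over the list alone, median 1.43), with PGAM1 (3.26) and LDHA (3.29). Heat shock genes had 14 up and 1 down of 18 (14 and 1 adjusted over the list alone, median 1.85). Endoplasmic reticulum stress and amino acid synthesis had 23 up and 2 down of 32 (23 and 2 adjusted over the list alone, median 1.2), with WARS1 (3.89) and MTHFD2 (3.86). Anti-apoptotic genes had 5 up and 3 down of 9 (5 and 3 adjusted over the list alone, median 0.69) and p53 targets 17 up and 6 down of 28 (17 and 6 adjusted over the list alone, median 1.01), with BIRC5 (7.27) and CDKN1A (3.59) up. Naive and quiescence genes had 1 up and 31 down of 33 (1 and 31 adjusted over the list alone, median -2.45), with IL7R (-4.66) and TSC22D3 (-4.45). T cell receptor signalling genes had 2 up and 25 down of 33 (2 and 25 adjusted over the list alone, median -0.59), with THEMIS (-1.93) and PTPRC (-1.99). Monocyte markers had 0 up and 10 down of 12 (0 and 10 adjusted over the list alone, median -3.00), NK and CD8+ markers 0 up and 9 down of 15 (0 and 9 adjusted over the list alone, median -1.68) and erythroid markers 4 up and 0 down of 4 (4 and 0 adjusted over the list alone, median 4.08). The haemoglobin genes HBD (5.34) and HBB (4.66) rose, and summed erythroid markers went from 2.07 ± 1.12 to 97.0 ± 97.1 CPM (88.8, 4.20 and 198 in donors 1, 2 and 3). Among these genes SEs were 0.12 to 0.63 and their highest edgeR adjusted p was 4.47e-06, for HBB. These 18 lists were called by camera (highest adjusted p = 0.0410). With an estimated correlation 0 were (10 at an unadjusted p under 0.05, lowest adjusted p = 0.0744), and fry called 30. Among the lists not called were ribosomal proteins (5 up and 25 down of 72), interferon-stimulated genes (9 and 11 of 42) and elongation factors (18 and 9 of 39).

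Genes that rose on activation and fell with the drugs, or the reverse, were counted to see whether the drugs moved activated cells against the activation change. IL17F, CCL17 and LIF rose on activation (9.46, 8.90 and 7.84) and fell with the drugs in activated cells (-1.89, -1.83 and -1.52), CCL17 not without donor 2, without the donor block or with DESeq2, and IL17F not without the block. MX2 fell on activation (-2.70) and rose with the drugs (1.51, or 0.53 without donor 2, not called then, without the block or in thinned libraries). In all, 326 genes changed in opposite directions. Of them 145 went up and then down, where independent lists would share 59.8, and 181 down and then up (106). In the same direction changed 42 genes, 29 up (96.3 for independent lists) and 13 down (65.9). Both comparisons use the activated DMSO libraries, so chance in these alone gives opposite changes. In 20 simulations of unchanged drug groups the count (median 1.5, highest 4) cannot weigh the 326, as few genes can be called. Across genes (not independent replicates) Pearson r was -0.377 (rho -0.383), simulated median -0.0798. The covariance was -0.290 against -0.0420 (difference -0.248). As 3 controls cannot be split with 2 in each part, part of the excess may come from shared controls. Without donors 1, 2 and 3 the count was 121, 10 and 186, and without the donor block 49.

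Genes of the mitochondrial genome took 8.93 ± 0.670% and 12.7 ± 2.13% of counts in DMSO and treated resting cells, higher with the drugs in 3 of 3 donors (exact two-sided sign-flip p = 0.25, the smallest that 3 donors allow). In activated cells they took 9.54 ± 0.676% and 10.4 ± 0.178%, also higher in 3 of 3 donors (exact sign-flip p = 0.25). Ribosomal protein genes took 27.8 ± 2.96% and 30.4 ± 1.81% in DMSO and treated resting cells, higher in 2 of 3 donors (exact sign-flip p = 0.5), a difference of 2.63 points. It was 0.912 without donor 1, 4.88 without donor 3 and 4.33 among counts outside mitochondrially encoded genes. In activated cells they took 20.8 ± 1.85% and 21.5 ± 3.05%, higher in 2 of 3 donors (exact sign-flip p = 0.75), a difference of 0.672 points that was -0.376 without donor 2. The 20 most abundant genes of each library took 20.1 ± 1.58% and 25.0 ± 1.34% in resting cells without and with the drugs, higher in 3 of 3 donors (exact sign-flip p = 0.25). In activated DMSO cells they took 16.2 ± 0.813%. Genes with at least 1 count numbered 22787 ± 3688 and 20409 ± 1947 in DMSO and treated resting libraries, fewer with the drugs in 2 of 3 donors (exact sign-flip p = 0.5). The difference was -2378, or -1490 without donor 1 and -3597 without donor 3, and total counts were lower in 3 of 3 donors (exact sign-flip p = 0.25). RNA concentrations were equalised before library preparation, so total RNA per cell was not measured.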

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

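The tests of unevenness between donors, of 1 donor alone and of cells of another type were chosen after the result was seen, and thinning was added after the data were seen, before its own result. The others were chosen before their results were seen.

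The drug effects in resting and activated cells differed by a test of the difference itself, the interaction, for 1408 genes (edgeR). Among the named genes the log2 difference, activated minus resting, was 3.02 for CCNE1, 3.02 for MX2, 2.84 for OAS1, 2.71 for IFI6, 2.56 for MX1, 2.54 for DPEP2, 2.46 for ISG15, 2.38 for HELZ2 and 1.51 for MYC. It was -3.60 for MTFR2, -2.60 for HAVCR2, -2.53 for MAEA, -2.24 for GCNA, -2.17 for CENPA, -2.00 for COQ3, -1.98 for STARD4-AS1 and -1.94 for MAFK. The interaction was also called for 11 lists, with camera adjusted p = 1.88e-09 (interferon-stimulated genes), 2.88e-06 (ribosomal proteins), 4.17e-05 (mitochondrially encoded genes), 5.62e-04 (naive genes), 0.00198 (ribosome biogenesis), 0.00848 (nuclear oxidative phosphorylation), 0.00848 (histone genes), 0.0106 (PP2A), 0.0211 (endoplasmic reticulum stress), 0.0241 (elongation) and 0.0406 (G2/M), of which 0 held with an estimated correlation (lowest adjusted p = 0.562). Outside the genes, the plasmid sequence in the table had 58.5 to 195 counts in every library, DMSO libraries included, and spike-in sequences at most 6 counts in a library. Groups held 3 libraries, so no library was tested for standing apart from its group.

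More genes were called with the drugs in resting than in activated cells (4122 and 462). Depth may not account for this: in 10 draws with every library thinned to the same total, resting cells gave at least 13.7 times as many calls. A larger spread between donors in activated cells was weighed with the covariance of 2 donors' log2 differences, which noise does not inflate, and its lowest value in resting cells was 2.70 times the highest in activated cells. Scaling left a ratio of calls of at least 8.77 over 4 scalings. The tables thus argue against these 3 as the whole cause, and a difference between the states, which the design names, remains a hypothesis, with cell loss and total RNA per cell unmeasured.

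Interferon-stimulated genes were higher with the drugs in activated cells, unevenly between donors: the median log2 difference of the 42 tested members was 0.217 in donor 1, 1.71 in donor 2 and 1.06 in donor 3 (29, 42 and 42 members higher), so the size of the change differed between donors. A change in 1 donor alone is argued against by the second highest of these medians, 1.06, and a difference in depth by the lowest median over 10 thinned draws, 0.905. Summed markers of monocytes and dendritic cells rose by at most 0.0147 of the rise of the list in any donor. This argues against RNA of such cells as the source of the rise. It cannot exclude a few cells that make interferon, and only 3 of 10 dendritic markers were tested. Monocyte markers summed to 38.9 ± 5.61 CPM in activated treated cells. A response to interferon made in some cultures may be part of it and stays open, and donors differ in ways that the design does not separate.

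The 10 splits of the libraries into 3 and 3 are too few for a share under 0.05, so the lowest share is 0.1. Other splits mix both conditions in each group, which widens the spread, so their few calls do not measure chance. For drugs in resting cells the real split called 4122 genes and the others 0 (102 to 1010 at an unadjusted p under 0.05, edgeR). For activated cells it called 462 and the highest other 33, and for activation 9174 and the others 0 (16 to 643). For the interaction, with a block per donor and state, the counts were 2411 and 0 (96 to 922). In each case only the real split called as many. Other splits parting all 3 pairs gave 0 calls, and the split with 33 calls parts 1 pair.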

How the results depend on the processing

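Thinning and leaving out overlapping genes were chosen after the data were seen. No direction turned over among the called genes named in the text, and where a count moved beyond 1.5 times the cause was not tested, except that stricter thresholds lower it by construction. For the drugs in resting cells (4122 genes) the counts were 2536 thinned, 2312 at 0.01, 1625 with a 2-fold minimum and 1869 to 3888 with 1 donor left out. For activated cells (462) they were 64 without the replicate block, 1117 with a block per donor and state, 1007 on 6 libraries, 750 with limma-voom, 179 thinned, 127 at 0.01, 192 with a 2-fold minimum and 13 to 265 with 1 donor left out. For activation (9174) the count was 5688 with a 2-fold minimum and 7016 to 9626 with 1 donor left out. For the interaction (1408) they were 2177 with library size alone, 573 without the block, 2411 with 6 blocks, 611 thinned, 393 at 0.01, 769 with a 2-fold minimum and 145 to 965 with 1 donor left out. All other settings stayed within 1.5 times. Lists called by camera, 5, 11, 18 and 11 in these contrasts, came to 0 in each with an estimated correlation and to 11, 5, 30 and 0 with fry, to 3 and 6 without the block for resting and activated cells, and to 4 to 5, 6 to 14, 17 to 19 and 6 to 11 with 1 donor left out. The correlation between states (0.333) was 0.268 to 0.319 with 1 donor left out. Genes higher in both (123) came to 77 with library size alone, 28 without the block and 3 to 64 with 1 donor left out, and those lower in both (80) to 7 and 3 to 39. Opposite changes (326) came to 49 without the block and 10 to 186. Outside mitochondrially encoded genes, the share of the 20 most abundant genes rose by 3.40 points with the drugs in resting cells, not 4.94, and changed by -5.87 points on activation, not -3.90. With 1 donor left out, the drugs' difference in activated cells was -0.376 to 1.71 points for ribosomal proteins and -1186 to 490.5 detected genes, and that of activation -878 to 46 detected genes. Of the genes named as changed, those that kept their call were, in resting cells, 78 of 85 without the block, 80 of 85 with library size alone, 80 of 85 with DESeq2, 77 of 84, 76 of 84 and 82 of 85 without donors 1, 2 and 3. In activated cells they were 7 of 55, 46 of 55, 40 of 55, 39 of 55, 9 of 55 and 40 of 55, in the interaction 29 of 43, 35 of 43, 43 of 43, 25 of 43, 13 of 43 and 33 of 43, and on activation 56 of 56 without the block. At 0.01 they were 82 of 85, 29 of 55 and 29 of 43 in the first 2 contrasts and the interaction, and with depth thinned to the lowest total 77 of 81, 38 of 54 and 31 of 41. The 7 of 55 kept without the block are named above.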

Other observations

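The odds ratio by expression level and the interferon genes were chosen after the result was seen.

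Calls of long non-coding RNA genes were split otherwise than those of protein-coding ones. With the drugs in resting cells 359 of them rose and 244 fell, against 1558 and 1883 protein-coding genes (odds ratio 1.78, 95% interval 1.49 to 2.13 of rising rather than falling), and with library size alone 232 and 417 against 505 and 3409 (odds ratio 3.75). Without donors 1 and 2 the odds ratio was 2.62 and 2.78. As a class they took 5.87 ± 1.06% of counts with DMSO and 6.03 ± 0.646% with the drugs, higher in 2 of 3 donors (exact sign-flip p = 0.75). In activated cells 125 rose and 12 fell, against 154 and 164 (odds ratio 11, 95% interval 5.81 to 22.8), but without donor 2 the counts were 1 and 1 against 3 and 8 (odds ratio 2.45, 95% interval 0.0255 to 234). Without donor 1 the odds ratio was 3.69 and without the donor block 5.97. It was 6.03 within deciles of mean expression and 9.90 within quintiles of gene span. Among genes that no other gene overlaps it was 3.74, with an interval of 0.684 to 38.4 that includes 1. On activation the direction was the other way, 269 up and 1075 down against 3983 and 3640 (odds ratio 0.229, 95% interval 0.198 to 0.264), or 0.394 within deciles of expression and 0.147 without overlapped genes. MALAT1, an abundant nuclear long non-coding RNA, took 0.859 ± 0.204% of counts in resting DMSO cells and 0.231 ± 0.0310% in activated ones (-1.80 ± 0.20, edgeR adjusted p = 3.98e-07, lower in 3 of 3 donors).

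IFNB1, which encodes interferon β, had 0 counts in the 3 activated DMSO libraries and 14 in the activated treated library of donor 2, with 0 in those of donors 1 and 3. In resting cells it had 0 counts with DMSO and 1 with the drugs, also in donor 2. IFNG was at 1186 ± 509 and 878 ± 143 CPM in activated cells without and with the drugs, higher in 1 of 3 donors and not called (-0.34 ± 0.17, edgeR adjusted p = 0.303). IFNL1 had 6 and 8 counts there, and the other interferon genes in the table at most 3 in any group.

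The higher share of rising among called long non-coding than protein-coding genes in resting treated cells was weighed against 3 technical explanations. All odds ratio intervals treat genes as independent and hold no spread between donors. Their low expression is argued against by an odds ratio within deciles of mean expression (2.96) whose lower 95% bound was 2.42, and gene length by a lower bound of 1.64 within quintiles of gene span. Reads from overlapping genes are argued against by the genes that no other gene overlaps (odds ratio 2.81), with a lower bound of 1.5, while in activated cells this bound was below 1 and the explanation stays open. No biological explanation was tested, nor priming inside A-rich stretches of unspliced RNA, which stays open.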
